A study of Mus musculus with 2 samples.

How the data were processed

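Droplet-based single-cell RNA libraries were analysed from 2 pools of 6 tibialis anterior muscles, 1 pool from mobile and 1 from immobilized limbs. Per the submitters' processing notes, Cell Ranger 3.0.2, R 3.6.3 and Seurat 3.1.4 were used; which step each tool served, and the genome build, are not given in the sources used here. The deposited matrices hold whole-number counts of UMIs per gene and barcode, and no normalization of them by the authors is recorded in the labels. Each matrix came with a list of 55536 genes and a list of barcodes. All 55536 versioned gene identifiers with their symbols matched the GENCODE M21 annotation, so coordinates are given from it on GRCm38. The lists of both libraries share 77 barcodes.

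The group of each library came from its sample label. The names of the deposited files give the opposite condition, and the sources used here hold nothing that settles which is right, so the groups follow the labels and are written as labelled-mobile and labelled-immobile. The condition was never inferred from expression.

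Cells with at least 200 genes and at most 20% mitochondrial UMIs were kept. This left 2068 labelled-mobile and 1198 labelled-immobile barcodes. Doublets were called per library with Scrublet as implemented in scanpy 1.11.5, which marked 10 of 3266 cells (0.306%) and 3 of 9839 cells under the wider filter, so the caller has not worked here and doublets remain. The 5% of cells with the highest scores were therefore removed as an added alternative. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes gave 30 principal components, a graph of 15 nearest neighbours and Leiden clusters at resolution 1.0 over both libraries without integration (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15). The 25 clusters fell into 13 classes.

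Clusters were named from marker lists of 19 cell types fixed before the data were examined. A name needed at least 3 of its markers at 2-fold or more over clusters of other types, at least 1 of them among the 10 leading genes, and no other type with more there. This procedure was revised more than once after the clusters were seen: folds were first taken against all other cells, which left endothelial clusters unnamed, and then against clusters of other candidate types, with the candidate set by the number of markers among the 20 leading genes. Under the wider filter 30 of 31 clusters were named, and the unnamed cluster, led by interferon-induced genes, held 193 labelled-mobile and 186 labelled-immobile cells (3.53% and 4.25%). Its candidate type was endothelial, with 25 endothelial markers at 2-fold or more but 0 among its 10 leading genes. Its cells were therefore left out of the endothelial-like class under that filter.

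Raw UMIs were summed per class and library and expressed as CPM of the class total. Exact Poisson intervals are given for CPM, exact Clopper-Pearson intervals for shares and exact conditional binomial intervals for ratios, all at 95% and for counting error only. Ratios are log2 of the labelled-immobile over the labelled-mobile value. A count of 0 was set to a floor of 3 counts, both for lower bounds of ratios and for the CPM that a count of 0 allows. With 1 library per group no test between conditions was made, and cells were not treated as replicates. Classes needed at least 100 retained cells in each library, which endothelial-like and FAP-like cells reached. The wider filter of at least 500 genes and at most 50% mitochondrial UMIs was added after seeing the data for 5 more classes, with mitochondrial, ribosomal and haemoglobin genes left out of the totals.

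The rule for named genes was fixed before the data were examined. A gene needed at least 100 CPM and 50 UMIs in the library where it was higher and at least 10% of its highest CPM over the classes of that library. Mitochondrial, ribosomal protein, haemoglobin and lymphocyte receptor genes were left out. Genes were ranked by the bound of the counting interval nearest 0. The first 10 in each direction were taken in pericyte-like cells, of which 1 is not reported here, the first 5 in endothelial-like and FAP-like cells and the first 3 in other classes. Genes with a log2 ratio of at least 1 in size and the same sign in at least 4 classes, with 50 UMIs in each, were named as well. Canonical pericyte and muscle stem cell genes were given whatever their values.

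Of 25 gene lists fixed beforehand, each with at least 4 members of at least 20 UMIs in a class was summarised by the median log2 ratio, after adding 0.5 counts to both sides. Its percentile among 10000 random lists matched on expression in 20 bins describes these libraries and is no test of the condition. The interval of a median came from 2000 Poisson draws of its counts.

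The procedures were tested on simulated data with 200 genes changed by known amounts. Both simulated libraries were Poisson draws from 1 pooled profile, without variation between cells or libraries, and the lists were randomly chosen genes. The simulation therefore checks the calculation alone. It cannot show how the intervals hold for counts clumped in a few cells, or the percentiles for genes that vary together. For the endothelial-like comparison over 11971 genes, true log2 changes of 0.5, 1 and 2 gave median estimates of 0.56, 1.02 and 2.03, and 96.0% of intervals held the true value. For the pericyte-like comparison over 10160 genes they gave 0.50, 1.02 and 1.94, and 5.5% of unchanged lists fell outside the central 95%. For the FAP-like comparison over 9503 genes they gave 0.43, 1.03 and 1.93.

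Alternatives fixed beforehand were a stricter filter (at least 500 genes, at most 10% mitochondrial UMIs), no filter, doublets kept, resolutions 0.5 and 2.0, classes from markers alone, variable genes without stress, mitochondrial and ribosomal genes, median-of-ratios scaling, totals without mitochondrial, ribosomal and haemoglobin genes, cells thinned to 1000 UMIs, other list floors and free-RNA limits, and another denominator for shares. Thinning left out 2 labelled-mobile and 0 labelled-immobile cells under the 20% limit. Added after seeing the data were the wider filter with its own set of alternatives, removal of the highest doublet scores, and leaving out the highest cell of each gene in each library. Figures were drawn with matplotlib 3.10.9.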

Results

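The study used unilateral hindlimb immobilization of male C57BL/6J mice aged 14 weeks. A staple held the right foot so that the tibialis anterior, the main dorsiflexor muscle of the lower leg, stayed shortened for 2 weeks, and muscles were taken on day 14. The left leg stayed mobile and served as the control. Mononuclear cells were released by digestion and captured in droplets with a single-cell kit that tags each captured RNA molecule with a unique molecular identifier (UMI). The 6 muscles of each condition were pooled into 1 library, so there were 2 libraries with 1 library per group. No replicate error could be had, and every interval given here covers counting error only.

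Groups were taken from the sample labels. The deposited file names carry the opposite condition: the files of the sample labelled mobile are named for the immobile limb, and the reverse. The libraries are therefore called the labelled-mobile and the labelled-immobile library, and every direction below would turn round if the file names hold. The labelled-mobile library held 11676 barcodes and 31215860 UMIs, with a median of 1618 UMIs and 400 genes per barcode. The labelled-immobile library held 11055 barcodes and 30021460 UMIs, with a median of 1681 UMIs and 287 genes. The median mitochondrial share of UMIs per barcode was 47.8% in the labelled-mobile and 66.6% in the labelled-immobile library. After the cell filter of at least 200 genes and at most 20% mitochondrial UMIs, and removal of called doublets, 2063 and 1193 cells were retained, with median depths of 6020 and 7305 UMIs. A wider filter, chosen after seeing the data, kept barcodes with at least 500 genes and at most 50% mitochondrial UMIs. It left 5464 cells of the labelled-mobile and 4372 cells of the labelled-immobile library, with median mitochondrial shares of 23.8% and 28.1%.

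The first comparison asked which cell types the mobile and immobilized muscles yielded. Endothelial-like cells were the largest class in both libraries, at 55.1% (exact binomial 95% interval 52.9 to 57.2) of the labelled-mobile and 49.4% (46.5 to 52.2) of the labelled-immobile cells. The stricter filter kept 385 labelled-mobile and 184 labelled-immobile cells over all classes. Under it the log2 ratio of endothelial-like shares turned from -0.16 to 0.02. Cells like fibro-adipogenic progenitors (FAPs), the matrix-producing stromal cells of muscle, were 7.90% (6.77 to 9.15) of the labelled-mobile and 13.9% (12 to 16) of the labelled-immobile cells. Pericyte-like cells, which wrap capillaries, were 8.53% (7.36 to 9.82) and 6.54% (5.20 to 8.09), and the interval of their log2 ratio of -0.38 reached from -0.79 to 0.01. Smooth muscle-like cells were 5.72% (4.76 to 6.81) of the labelled-mobile and 7.96% (6.49 to 9.65) of the labelled-immobile library. Muscle stem cell-like cells were 6.06% (5.07 to 7.18) and 5.70% (4.45 to 7.17), a difference not detectable at this depth. Schwann and glial-like cells were 4.56% (3.70 to 5.55) and 2.51% (1.70 to 3.57), a log2 ratio of -0.86 that was -1.52 under the stricter filter. Macrophage-like cells were 1.79% (1.27 to 2.46) and 3.35% (2.41 to 4.54), while monocyte-like cells were 1.75% (1.23 to 2.41) and 0.754% (0.346 to 1.43). Digestion, filtration and the limit on mitochondrial UMIs set which cells enter these shares. The monocyte-like cluster was led by S100a9, S100a8 and Il1b. Under the wider filter S100a9 and S100a8 led a separate neutrophil-like cluster of 47 and 21 cells, and the log2 ratio of monocyte-like shares was -0.86 (-1.84 to 0.06). The log2 ratio of shares was 0.82 for FAP-like and 0.90 for macrophage-like cells under the 20% limit, 0.28 and 0.74 under the wider filter, and -0.16 and -0.60 with neither a gene minimum nor a mitochondrial limit. Under the stricter filter the macrophage-like ratio was -1.60. Deposited barcodes had at least 818 UMIs in the labelled-mobile and 1041 in the labelled-immobile library. The ratios with neither a gene minimum nor a mitochondrial limit therefore compare barcodes cut at unlike depths.

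**Figure D1:**
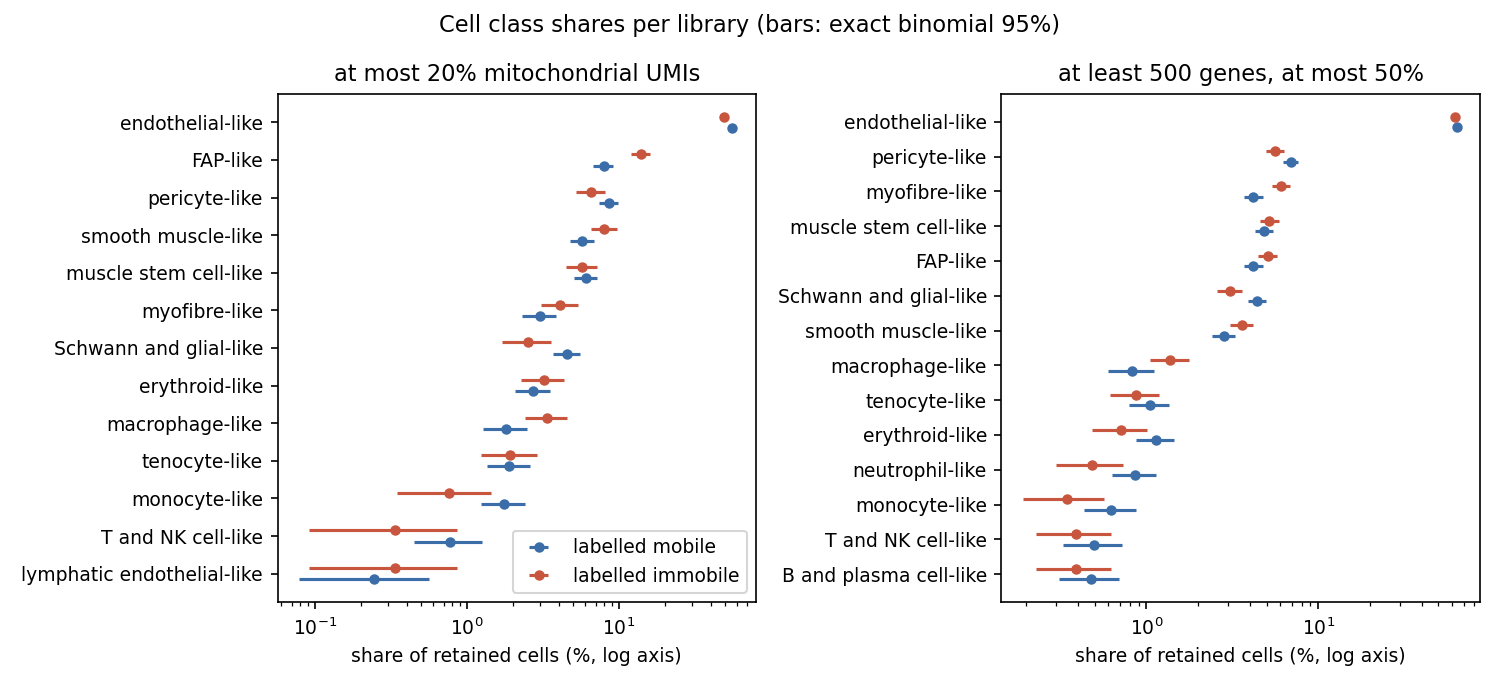
Share of retained cells (%, log axis) in each named cell class, for the labelled-mobile (blue) and labelled-immobile (red) library, under the 20% mitochondrial limit (left) and the wider filter (right); points are shares and bars exact binomial 95% intervals, covering counting error only. FAP-like cells stand at 7.90% and 13.9% on the left and at 4.19% and 5.08% on the right.

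Gene levels in endothelial-like cells were compared over 1136 labelled-mobile and 589 labelled-immobile cells, with 7295421 and 4504672 UMIs. By the sample labels, which the file names contradict, Rbp7 (a retinol-binding protein; ENSMUSG00000028996.9, GRCm38 chromosome 4, 149449687 to 149454978) stood at 148 CPM (UMIs scaled to a common class total; Poisson interval 139 to 157) in the labelled-mobile and 263 CPM (248 to 278) in the labelled-immobile library. The other genes named on that side were Plvap (fenestral diaphragm protein, log2 ratio of immobile over mobile 0.84), Edn1 (the vasoconstrictor endothelin 1, 0.81), Igfbp3 (0.73, and 1.34 under the stricter filter) and Stmn2 (0.74). On the other side Tmem252 was 3.20-fold higher in the labelled-mobile library, at 116 CPM (109 to 124) against 36.4 CPM (31.0 to 42.4), with a log2 ratio of -1.68 that was -2.28 without a cell filter. The log2 ratio was -0.84 for Adamts9 and -0.72 for Adamts1, both secreted proteases, -0.73 for the immediate early transcription factor Egr1 and -0.80 for Ugcg. The largest cluster of endothelial-like cells had 349 labelled-mobile and 124 labelled-immobile cells by the labelled-mobile count. By the labelled-immobile count it was another, of 311 and 200 cells. Aqp1, Timp4, C1qtnf9 and Gpihbp1 led both, so these genes do not set them apart. Several of the named genes lead clusters within the class, so their values also reflect which clusters each library holds. Rbp7, Igfbp3, Stmn2 and Edn1 lead clusters headed by Btnl9 and by Sema3g, and Plvap leads 1 headed by Selp. Tmem252 and Adamts9 lead a cluster of 72 labelled-mobile and 5 labelled-immobile cells.

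Of 24 gene lists that could be measured in endothelial-like cells, 7 had a median outside the central 95% of 10000 random lists with a counting interval that excluded 0. The immediate early and dissociation response list had 13 of 14 members higher in the labelled-mobile library and a median log2 ratio of -0.29 (-0.34 to -0.22), with Fosb at -0.70, Zfp36 at -0.39 and Btg2 at 0.02. The metallothionein and glucocorticoid response list had a median of -0.34 (-0.47 to -0.14), with the metal-binding Mt1 at -1.41 and Mt2 at -1.71. Inflammatory cytokines and NF-kB targets had a median of -0.12 (-0.29 to -0.02), inside the random lists. Under the wider filter their median was -0.41 (-0.53 to -0.24), outside the random lists, with all 10 measured members higher in the labelled-mobile library. Glycolysis had 11 of 13 members higher in the labelled-immobile library and a median of 0.23 (0.16 to 0.29), at percentile 99.98 of the random lists, with Pfkl at 0.59, Eno1 at 0.48 and Gapdh at 0.23. Antigen presentation by MHC class II had all 5 measured members higher in the labelled-immobile library with a median of 0.92 (0.60 to 1.29), on low counts: Cd74 had 143 and 193 UMIs. That median was 0.33 without each gene's highest cell, 0.12 under the wider filter and 0.04 without a cell filter. Macrophages also express these genes; their share was higher in that library under the 20% limit and the wider filter, and lower under the stricter filter and without a filter. The pericyte identity list, whose genes pericytes express, had a median of -0.63 (-0.85 to -0.19) in endothelial-like cells, beside the lower pericyte-like share of the labelled-immobile library. Collagens, which FAPs express most, had a median of -0.51 (-0.81 to -0.08) over 7 members. The FAP-like share went the other way, at 7.90% of labelled-mobile and 13.9% of labelled-immobile cells. Haemoglobins had a median of -3.64 (-3.79 to -3.42), on a blood transcript that red cells can bring to other droplets, and the median was -1.33 under the wider filter, -0.77 with classes from markers alone and -5.35 under the stricter filter.

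FAP-like cells were compared over 163 labelled-mobile and 166 labelled-immobile cells, with 1218626 and 1375336 UMIs. By the same labels, Has1, which makes hyaluronan, stood at 184 CPM (161 to 210) in the labelled-mobile and 777 CPM (731 to 825) in the labelled-immobile library, a 4.22-fold ratio. Its UMIs came from 26 and 50 cells. Ptgs2, the inducible cyclooxygenase, stood at 204 CPM (180 to 231) and 752 CPM (707 to 799), from 25 and 55 cells. Sfrp4, a secreted Wnt inhibitor, stood at 45.1 CPM (34.0 to 58.7) and 172 CPM (150.4 to 195), a log2 ratio of 1.93 that was 1.08 under the stricter filter. The log2 ratio was 1.44 (1.33 to 1.54) for the secreted glycoprotein Myoc and 1.44 (1.26 to 1.63) for Ugdh, which makes the UDP-glucuronate used for hyaluronan. Has1 and Ptgs2 were among the leading genes of a FAP-like cluster headed by Pi16, which held the largest part of the labelled-immobile FAP-like cells, while a cluster headed by Cxcl14 and Smoc2 held the largest part in the labelled-mobile library.

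The genes named as higher in the labelled-mobile FAP-like cells rested on few cells. Saa3, an acute-phase protein, had 304 UMIs from 3 cells and 0 UMIs in the labelled-immobile library, at least 114-fold higher against a floor of 3 counts over that class. The neutrophil-attracting chemokine Cxcl5 had 297 UMIs from 3 cells, 96.3% of them from 1 cell, and 0 UMIs in the other library, at least 112-fold higher. Lcn2, an iron-siderophore binder, had 281 UMIs from 16 cells and 0 UMIs, at least 106-fold higher. The matrix protein tenascin C, Tnc, had 258 UMIs from 4 cells and 3 UMIs, a log2 ratio of -6.60 (-8.89 to -5.04). The haemoglobin binder haptoglobin, Hp, had 134 UMIs from 3 cells and 1 UMI, a log2 ratio of -7.24 (-12.55 to -4.74). With cells thinned to 1000 UMIs, 19 UMIs of Saa3, 11 of Cxcl5, 21 of Lcn2, 5 of Tnc and 6 of Hp were left in the labelled-mobile library against 0, and the log2 ratios at the floor were -2.69, -1.90, -2.83, -0.76 and -1.03. Without each gene's highest cell they were -4.61 for Saa3, -2.05 for Cxcl5, -6.05 for Lcn2 and -3.68 for Hp, and Tnc stood at -6.70 (-12.02 to -4.18). Under the stricter filter Tnc stood at -4.92, and with classes from markers alone Saa3 stood at -4.79 and Cxcl5 at -2.23.

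In FAP-like cells 8 of 23 lists stood outside the random lists. Fibrillar and associated collagens had 11 of 12 members higher in the labelled-mobile library with a median of -0.24 (-0.29 to -0.16), from Col1a1 at -0.28 and Col3a1 at -0.27 to Col14a1, the exception, at 1.16. This median was -0.09 without each gene's highest cell and -0.04 with cells thinned to 1000 UMIs. The cell cycle list had all 14 members higher in the labelled-mobile library with a median of -1.10 (-1.29 to -0.88), with Mki67 at 82 and 44 UMIs and Top2a at 87 and 46 UMIs. These genes lead a cluster of 11 labelled-mobile and 3 labelled-immobile cells, which Tnc also leads, and the median was -0.02 without a cell filter. Inflammatory cytokines and NF-kB targets had 7 of 10 members higher in the labelled-immobile library with a median of 0.26 (0.07 to 0.49). Cxcl2 stood at 1.48 and Nfkbia at 0.64, against Cxcl10 at -0.86. Angiogenic signalling (-1.02, interval -1.26 to -0.64), contractile mural genes (-0.98, -1.44 to -0.58), adipogenic genes (-0.74, -1.58 to -0.43) and myofibre transcripts (-1.41, -1.67 to -1.25) had their medians on the labelled-mobile side. Endothelial, mural, fat and fibre cells express most members of these lists. Under the stricter filter, with 385 and 184 cells over all classes, the angiogenic median was 0.53, the myofibre median 0.27 and the contractile median -2.61. The contractile median was -1.89 with called doublets kept, -1.72 with members of at least 100 UMIs and -0.30 with classes from markers alone. Haemoglobins had a median of 4.27 (3.99 to 4.63) in the opposite direction to endothelial-like cells, of 7.56 under the stricter filter and of -1.45 without a cell filter.

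The study's question concerned pericytes. The 20% limit left 78 pericyte-like cells in the labelled-immobile library, below the 100 set beforehand, so pericyte-like cells and the classes below were compared under the wider filter. Mitochondrial, ribosomal and haemoglobin genes were left out of the totals there. The comparison covered 378 labelled-mobile and 245 labelled-immobile pericyte-like cells, with scaling totals of 1500962 and 962316 UMIs. They fell into a cluster of 208 and 151 cells, with a median of 2552 UMIs, and a cluster of 170 and 94 cells, with 8246.5. Under the 20% limit, a cluster with Gja4, Gja5 and Vegfc among its leading genes held 15 and 17 cells, and the other held 161 and 61. Values of the class therefore also reflect which clusters each library holds. By the sample labels, the pericyte genes Vtn, Higd1b and Kcnj8 were higher in the labelled-immobile library. Vitronectin, Vtn (ENSMUSG00000017344.4, GRCm38 chromosome 11, 78499091 to 78502324), stood at 1138 CPM (1085 to 1193) in the labelled-mobile and 1737 CPM (1655 to 1823) in the labelled-immobile library. Higd1b had a log2 ratio of 0.62 (0.41 to 0.83) and the potassium channel subunit Kcnj8 0.43 (0.31 to 0.54). Igfbp5, a binding protein of insulin-like growth factors (ENSMUSG00000026185.8, chromosome 1, 72857932 to 72874884), was 2.22-fold higher in the labelled-mobile library, at 613 CPM (574 to 654) against 276 CPM (244 to 312). The other canonical pericyte genes lay close together. Pdgfrb stood at 1261 and 1260.5 CPM, Mcam at 318 and 334 CPM, Cspg4 (the NG2 proteoglycan) at 249 and 292 CPM, and Rgs5 had a log2 ratio of 0.09 (0.06 to 0.13).

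Besides Vtn and Higd1b, the genes named as higher in labelled-immobile pericyte-like cells were Edn1 (log2 ratio 1.08), Plat, the tissue plasminogen activator (0.83), the lactate dehydrogenase subunit Ldhb (0.74), Adgre5 (0.71), Tppp3 (0.70), Bsg (0.62), the mitochondrial aldehyde dehydrogenase Aldh2 (0.59) and Gm28438 (0.44). The UMIs of Edn1 came from 31 labelled-mobile and 25 labelled-immobile cells. Gm28438 is annotated as an unprocessed pseudogene and its counts are uncertain, since it can take reads of mitochondrial transcripts. Besides Igfbp5, those named as higher in labelled-mobile pericyte-like cells were Rnd1 (-0.89, with 17 and 3 UMIs left in thinned cells), Mrpl52 (-0.74), Ddit4l (-0.73), Nus1 (-0.70), Rapgef5 (-0.70), Adamts1 (-0.67), Tmsb10 (-0.61) and the inducible heat shock gene Hspa1b (-0.49). Hspa1b has a near-identical relative, Hspa1a, and is uncertain for that reason.

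**Figure D2:**
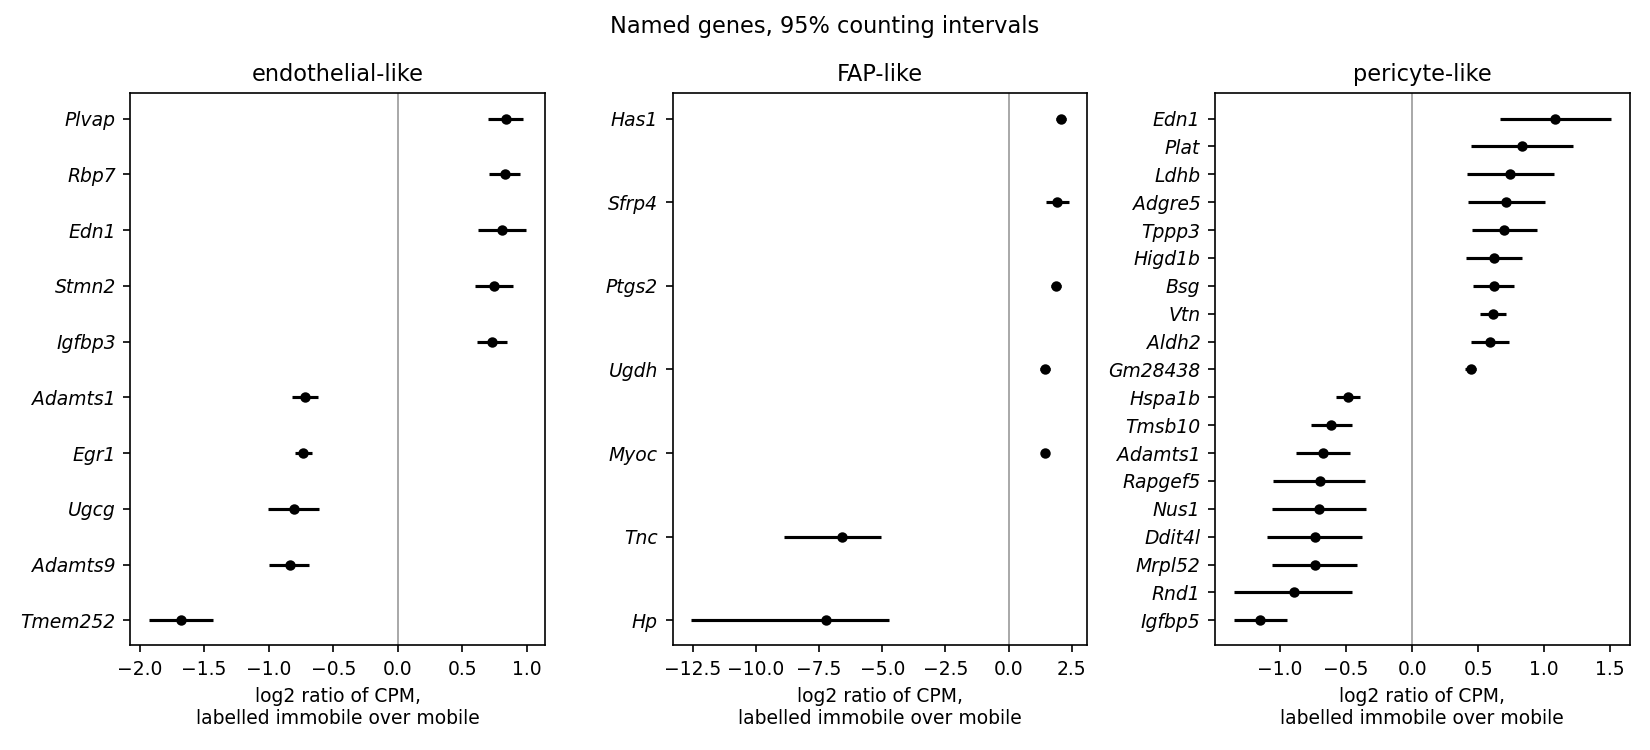
Log2 ratio of CPM, labelled-immobile over labelled-mobile library, for the genes named by rank and reported for endothelial-like, FAP-like and pericyte-like cells; points are ratios, bars are 95% counting intervals, and the horizontal axes differ between panels. Saa3, Cxcl5 and Lcn2 had 0 UMIs in 1 library and are not drawn, and in pericyte-like cells the ratios run from -1.15 for Igfbp5 to 1.08 for Edn1.

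Secreted trophic factors were sparsely counted in pericyte-like cells. Vegfa had 8 UMIs in the labelled-mobile and 4 in the labelled-immobile library, and Igf1 had 6 in each. Hgf had 0 UMIs in both, which allows up to 2.00 and 3.12 CPM. Cxcl12 was the exception, with 2833 and 3001 CPM and a log2 ratio of 0.08 (0.01 to 0.15). Fewer than 4 members of this list reached 20 UMIs, so it has no median here.

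In pericyte-like cells 11 of 21 lists stood outside the random lists. The contractile mural list had 9 of 10 members higher in the labelled-immobile library and a median of 0.33 (0.20 to 0.42), with Tagln at 1.09, the smooth muscle actin gene Acta2 at 0.71 and Tpm2 at 0.69. This median was 0.17 under the 20% limit and 0.13 without free-RNA members. The pericyte identity list had 9 of 10 members on the same side and a median of 0.27 (0.11 to 0.38), which was 0.07 under the 20% limit. Collagens had all 10 measured members on that side with a median of 0.31 (0.16 to 0.45), but the median was -0.46 under the 20% limit and -0.80 without the 5% of cells with the highest doublet scores. Inflammatory cytokines and NF-kB targets had a median of -0.74 (-1.73 to -0.10) with 7 of 9 members higher in the labelled-mobile library, on low counts such as 34 and 3 UMIs for Cxcl2 and 40 and 3 UMIs for Cxcl10, and was -2.71 without the highest doublet scores. The interferon response had all 14 members on that side and a median of -0.23 (-0.39 to -0.17), with Irf7 at -0.61. The immediate early list stood at -0.15 (-0.20 to -0.09) and turned to 0.05 under the 20% limit. Matrix remodelling stood at -0.21 (-0.41 to -0.03), but at 0.15 with members of at least 1 UMI, -1.06 without the highest doublet scores and -0.85 in thinned cells. Glycolysis stood at 0.17 (0.06 to 0.32), mitochondrially encoded genes at 0.40 (0.36 to 0.41), myofibre transcripts at -0.35 (-0.55 to -0.18) and haemoglobins at 1.27 (1.11 to 1.36). Under the 20% limit the haemoglobin median was -1.28 and the myofibre median -1.09, and without a cell filter the myofibre median was 0.37. Mitochondrial genes lay outside the totals, so the mitochondrially encoded medians here and in the classes below follow the mitochondrial shares of the retained cells. In pericyte-like cells the median share was 24.0% in the labelled-mobile and 29.3% in the labelled-immobile library.

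Smooth muscle-like cells, 154 labelled-mobile and 157 labelled-immobile, differed in early response genes. By the sample labels all 14 immediate early genes were higher in the labelled-mobile library with a median of -0.61 (-0.71 to -0.55), among them Ier3 at -1.04 and Zfp36 at -0.97. All 6 measured NF-kB targets were on that side too, with a median of -1.59 (-1.91 to -1.22). The NF-kB inhibitor gene Nfkbia stood at 539 CPM (493 to 588) against 206 CPM (178 to 238). Crispld2 was 3.42-fold and the protease gene Adamts4 3.21-fold higher in the labelled-mobile library, and thinning left 21 and 3 UMIs of Adamts4. Named on the labelled-immobile side were Rasl11b (1.06, and 1.92 in thinned cells), the chemokine scavenger receptor Ackr3 (1.00, and 1.65 thinned) and Ppp1r3c (0.97). Contractile genes had 10 of 11 members higher there with a median of 0.24 (0.19 to 0.26), which was 0.06 in cells thinned to 1000 UMIs, and pericyte identity genes a median of 0.32 (0.15 to 0.41). Medians on the labelled-mobile side were -0.50 (-0.70 to -0.22) for the TGF-beta response, -0.48 (-0.91 to -0.20) for the interferon response, -0.29 (-0.53 to -0.09) for metallothionein and glucocorticoid genes and -0.18 (-0.36 to -0.05) for the basement membrane. Mitochondrially encoded genes stood at 0.37 (0.36 to 0.40) and haemoglobins at -4.33 (-4.66 to -3.90), which was -1.45 without each gene's highest cell and -0.61 without the highest doublet scores.

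Muscle stem cell-like cells, 263 labelled-mobile and 227 labelled-immobile, had the satellite cell gene Pax7 at 825 CPM (log2 ratio -0.04, -0.22 to 0.13) and Myod1 at 336 CPM in the labelled-mobile library (-0.18, -0.47 to 0.10), neither distinguishable from the labelled-immobile values of 800 and 296 CPM. Myf5, a myogenic transcription factor, was higher in the labelled-immobile library, at 618 against 376 CPM (0.72, 0.49 to 0.95). Named beside it on that side were Nppc (C-type natriuretic peptide, 1.12), Msc (1.36, and 2.42 under the 20% limit) and the small heat shock gene Hspb1 (0.92). On the labelled-mobile side were Nnmt (-2.50), the interferon-inducible GTPase gene Iigp1 (-1.78) and the cell cycle inhibitor gene Cdkn1c (-1.59). Of the labelled-mobile UMIs of Cdkn1c 43.0% came from 1 cell, and the gene stood at -0.86 in thinned cells. Thinned cells kept 38 and 3 UMIs of Iigp1. Its labelled-mobile CPM was 11.1% of its highest class value in that library, just above the 10% limit. Iigp1 was also among the leading genes of an endothelial-like cluster of 710 labelled-mobile and 313 labelled-immobile cells, and a part from RNA of other cells was not tested. All 11 heat shock genes were higher in the labelled-immobile library with a median of 0.26 (0.21 to 0.33). The immediate early list had 9 of 14 members on that side and a median of 0.29 (0.25 to 0.32), opposite to smooth muscle-like cells. All 10 measured NF-kB targets were higher in the labelled-mobile library with a median of -0.94 (-1.13 to -0.70), including Ccl7 at -3.14. Secreted trophic factors (-0.76, -1.03 to -0.27), the TGF-beta response (-0.41, -0.65 to -0.16) and angiogenic signalling (-0.39, -0.75 to -0.18) lay on the same side, the last turning to 0.44 in cells thinned to 1000 UMIs. Myofibre transcripts stood at 0.58 (0.40 to 0.72), mitochondrially encoded genes at 0.27 (0.26 to 0.31) and haemoglobins at -6.51 (-6.82 to -6.17), which was -0.96 with classes from markers alone.

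Schwann and glial-like cells, 241 labelled-mobile and 134 labelled-immobile, had 10 of 11 interferon response genes higher in the labelled-mobile library by the sample labels, with a median of -1.11 (-1.42 to -0.56). That median was -0.10 under the 20% limit, which left 94 labelled-mobile and 30 labelled-immobile cells of this class. Named there were Spp1 (-1.22), Rgs2 (-1.54) and the nuclear receptor gene Nr4a2 (-0.89), at -2.88, -2.54 and -1.55 under the 20% limit. Lyz2, the lysozyme gene that macrophages express strongly, had a log2 ratio of 1.85 (1.72 to 1.98) toward the labelled-immobile library. Nbl1 stood at 1.37 (1.11 to 1.64) but turned to -1.30 with classes from markers alone. A cluster of this class, of 27 and 23 cells, had the perineurial markers Cldn1 and Lypd2 among its leading genes. Without a cell filter Nbl1 was among the leading genes of a FAP-like cluster with these 2 markers. Values of the class, that of Nbl1 among them, may therefore also reflect which clusters each library holds. Lgals7 stood at 2.84 (2.14 to 3.61) with 88.1% of its labelled-immobile UMIs from 1 cell, and at 0.84 without its highest cell in each library. The immediate early (-0.26), heat shock (-0.21), angiogenic (-0.36), myofibre (-0.29) and haemoglobin (-5.56) lists had their medians on the labelled-mobile side, and the glycolysis (0.24), contractile (0.37), pericyte identity (0.44) and mitochondrially encoded (0.33) lists on the other. The haemoglobin median turned to 2.66 under the 20% limit and was -1.04 with classes from markers alone, and the myofibre median was -1.53 under the 20% limit and 0.03 without the highest doublet scores. The cell cycle list had 4 of 5 members higher in the labelled-mobile library and a median of -2.56 (-4.65 to -1.19), or -1.89 with counts of 0 at the floor. With members of at least 1 UMI the pericyte identity median was 1.21.

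Myofibre-like barcodes, 229 and 266, can be fibre fragments or droplets rich in fibre RNA, since the suspension was filtered for mononuclear cells. Ankrd1, a stretch-responsive cardiac ankyrin repeat gene, was 9.40-fold and cardiac actin, Actc1, 4.09-fold higher in the labelled-mobile library, and F830016B08Rik 9.84-fold. Without its highest barcode in each library, Ankrd1 kept 59 and 3 UMIs. Fhl1 stood at 189 CPM (157 to 225) in the labelled-mobile and 515 CPM (465 to 570) in the labelled-immobile library. Cuedc2 had a log2 ratio of 1.37 (0.77 to 1.99) and Nts, with 20 and 103 UMIs from 4 and 7 barcodes, 2.19 (1.49 to 2.96), but 0.05 with classes from markers alone and 3.39 without its highest barcode in each library. Glycolysis had 11 of 12 members higher in the labelled-immobile library with a median of 0.25 (0.20 to 0.37), and mitochondrially encoded genes a median of 0.40 (0.36 to 0.43), which was -0.05 under the 20% limit. The contractile mural median of -1.03 (-2.06 to -0.17) was 0.03 without each gene's highest cell. Haemoglobins stood at -4.63 (-5.04 to -4.30), but at -0.46 without each gene's highest cell, -0.31 with classes from markers alone and -1.13 without a cell filter. The growth arrest and muscle atrophy list had a median of -0.07 (-0.58 to 0.15) over 7 members, inside the random lists.

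Across the 7 classes compared under the wider filter, Adamts4 had a log2 ratio of at least 1 in size in 4 classes, all toward the labelled-mobile library, with a median of -1.47. The haemoglobin genes Hba-a1, Hba-a2 and Hbb-bs met the same rule in 5 classes, with medians over these 5 of -4.85, -4.90 and -5.05. In the other 2 classes the haemoglobin list had all 4 members higher in the labelled-immobile library, with medians of 4.21 in FAP-like and 1.27 in pericyte-like cells under that filter.

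**Figure D3:**
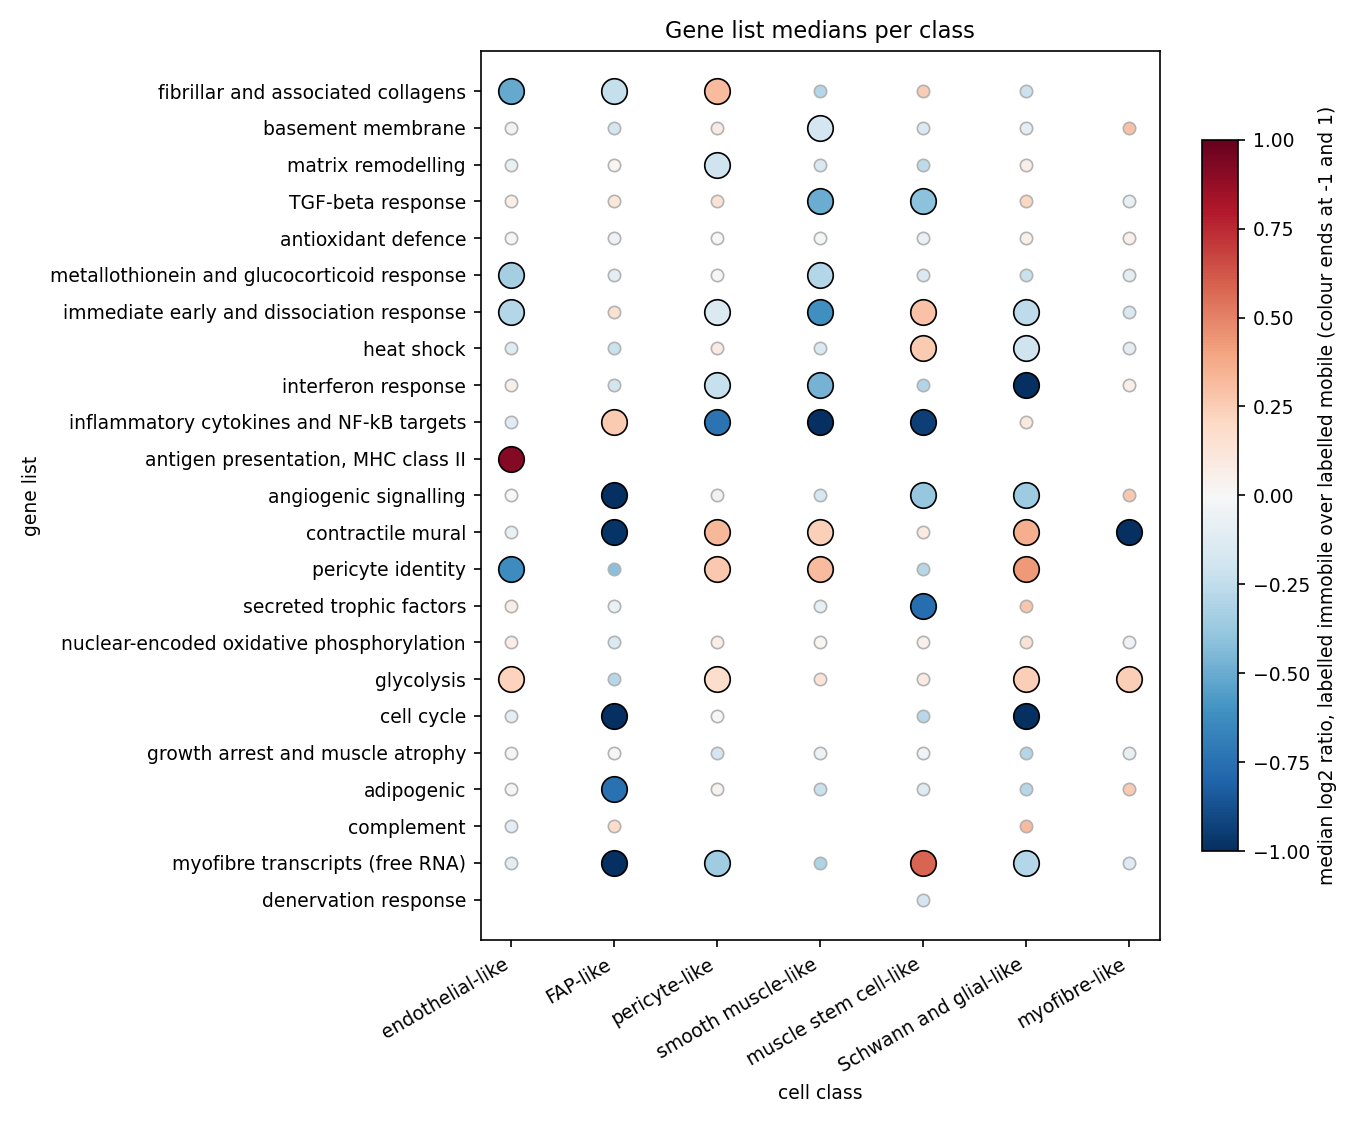
Median log2 ratio, labelled-immobile over labelled-mobile library, of each gene list (rows) in each cell class (columns), as colour; large points with a black rim have a median outside the central 95% of random lists and a counting interval that excludes 0, small points do not, and an empty place means fewer than 4 measured members. The haemoglobin and mitochondrially encoded lists are not drawn, and the NF-kB list runs from -1.59 in smooth muscle-like to 0.26 in FAP-like cells.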

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

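The tests of single cells and of the mitochondrial limit in this part were chosen after the opposite directions of the immediate early genes had been seen.

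Barcodes left out by both cell filters carried a muscle fibre signal that the comparisons did not use. Myofibre-like barcodes were 35.1% (2171 of 6185, exact binomial interval 33.9 to 36.3) of these barcodes in the labelled-mobile and 43.1% (2873 of 6664, 41.9 to 44.3) in the labelled-immobile library. The median barcode there had 141 and 142 genes and mitochondrial shares of 79.4% and 82.8%. The deposited barcodes had at least 818 UMIs in the labelled-mobile and 1041 in the labelled-immobile library. Without a cell filter the median myofibre-like barcode had 969 and 1246 UMIs. The 2 shares therefore come from sets of barcodes cut at unlike depths and are not directly comparable.

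The immediate early and dissociation response list went opposite ways in muscle stem cell-like cells, with a median log2 ratio of 0.29, and in smooth muscle-like cells, with a median of -0.61; the difference was not tested across replicates, since there were none. Under the same wider filter it stood at -0.44 in endothelial-like, -0.15 in pericyte-like, -0.26 in Schwann and glial-like, -0.16 in myofibre-like and 0.29 in FAP-like cells, with the pericyte-like median turning to 0.051 under the 20% limit. Single cells with very high counts do not account for the opposite directions, since the difference was 0.93 (0.82 to 1.06) without the highest cell of each gene. Under the 20% mitochondrial limit the medians were 0.15 and -0.41 and their difference 0.56 (0.45 to 0.74), so a part played by the wider limit cannot be told apart from the rest, on 68 labelled-immobile muscle stem cell-like cells. A harsher digestion of 1 pool that acted unequally on the classes stays open, as does an effect of immobilization, and which library was immobilized is itself open because labels and file names disagree.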

How the results depend on the processing

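The wider filter, the removal of the highest doublet scores or of each gene's highest cell, and all alternatives for the classes of the wider filter were chosen after seeing the data, as was the choice of the list medians given most weight here. Of 741 values of 64 named gene results under the alternatives, 642 stayed within the counting interval with the same direction, 97 moved and 2 reversed. Of 817 values of 60 list medians, 638 stayed, 151 moved and 28 reversed. Of 85 values of 9 share ratios, 78 stayed, 3 moved and 4 reversed. A share ratio whose interval held 0 was not counted as reversed when its sign changed. The muscle stem cell-like ratio, -0.09 under the 20% limit and 0.11 under the wider filter, thus counts as stayed. No paired analysis was possible because there was 1 library per group and no test was made, and leaving out each library in turn was not possible for the same reason. The stricter filter and the keeping of called doublets were not repeated for the classes of the wider filter. Without the free-RNA limit, 3 of the 6 named genes stayed in smooth muscle-like and 3 of 6 in myofibre-like cells. All values below are log2 ratios or list medians, labelled-immobile over labelled-mobile, and the cause of each difference was not tested.

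The stricter filter kept 385 labelled-mobile and 184 labelled-immobile cells over all classes. Under it the share ratio was 0.025 for endothelial-like, -0.91 for pericyte-like, -1.52 for Schwann and glial-like and -1.60 for macrophage-like cells. The immediate early median in endothelial-like cells was -0.16 there, and in FAP-like cells collagens were at -0.44, angiogenic signalling at 0.53, cell cycle at -1.37 and myofibre transcripts at 0.27. Without a cell filter the share ratio was -0.16 for FAP-like and -0.60 for macrophage-like barcodes. The deposited barcodes reached down to 818 labelled-mobile and 1041 labelled-immobile UMIs. Endothelial-like immediate early genes were then at -0.56 and glycolysis at 0.11, FAP-like cell cycle at -0.018 and haemoglobins at -1.45, pericyte-like collagens at 0.036, contractile genes at 0.42 and myofibre transcripts at 0.37, and Schwann and glial-like interferon genes at -0.35 and haemoglobins at 2.04. Under the wider filter the FAP-like share ratio was 0.28, the endothelial-like immediate early median -0.44 and the FAP-like cell cycle median -1.91.

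Under the 20% limit, pericyte-like collagens were at -0.46, immediate early genes at 0.051, contractile genes at 0.17, identity genes at 0.070 and haemoglobins at -1.28. Smooth muscle-like contractile genes were at 0.28, muscle stem cell-like NF-kB targets at -1.36, Schwann and glial-like interferon genes at -0.096 and haemoglobins at 2.66, myofibre-like contractile genes at 0.12 and mitochondrially encoded genes at -0.046.

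With cells thinned to 1000 UMIs, endothelial-like immediate early genes were at -0.34, FAP-like collagens at -0.043, pericyte-like myofibre transcripts at 0.031 and smooth muscle-like contractile genes at 0.060. Muscle stem cell-like heat shock genes were at 0.35 and angiogenic genes at 0.44, Schwann and glial-like interferon genes at -0.41 and myofibre transcripts at 0.065, and myofibre-like contractile genes at 0.0062. With classes from markers alone, FAP-like collagens were at -0.14 and cell cycle genes at 0.0045, pericyte-like collagens at 0.11 and haemoglobins at -0.50, smooth muscle-like NF-kB targets at -1.97 and contractile genes at 0.28, Schwann and glial-like Nbl1 at -1.30 and myofibre-like contractile genes at 0.059. Without the highest doublet scores, FAP-like myofibre transcripts were at 0.040, pericyte-like collagens at -0.80 and NF-kB targets at -2.71, smooth muscle-like NF-kB targets at -1.15, Schwann and glial-like Nbl1 at -0.65 and myofibre transcripts at 0.028, and myofibre-like contractile genes at 0.088.

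Without each gene's highest cell, FAP-like collagens were at -0.094, cell cycle genes at -1.46 and myofibre-like contractile genes at 0.034. Median-of-ratios scaling put FAP-like collagens at -0.15, and totals of all genes put smooth muscle-like contractile genes at 0.18 and muscle stem cell-like heat shock genes at 0.20. Pericyte-like collagens were at -0.0025 at resolution 0.5 and at -0.0057 with variable genes chosen without stress, mitochondrial and ribosomal genes. With members of at least 1 UMI, pericyte-like matrix remodelling was at 0.15 and Schwann and glial-like interferon genes at -0.53, and with members of at least 100 UMIs myofibre-like contractile genes were at 0.00041. Without free-RNA members, contractile genes were at 0.13 in pericyte-like and 0.0099 in myofibre-like cells, and Schwann and glial-like interferon genes at -0.42.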

Other observations

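The tests of a few cells, of the dissociation response and of the Pi16-led cluster alone in this part were chosen after their results or closely related values had been seen; those of neutrophil RNA and of Pi16 markers were not.

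Beyond the 4 classes named in the report, glycolysis genes had medians inside the random lists, of 0.14 in smooth muscle-like, 0.09 in muscle stem cell-like and -0.29 (-0.45 to -0.10) in FAP-like cells. Nuclear-encoded genes of oxidative phosphorylation had medians of 0.07 in pericyte-like and -0.15 in FAP-like cells, both inside the random lists. Antioxidant defence genes had medians between -0.06 in muscle stem cell-like and 0.06 in Schwann and glial-like cells, inside the random lists in all 7 classes. The denervation response, measured in muscle stem cell-like cells, had a median of -0.18 (-0.54 to -0.02) over 5 members, inside the random lists at percentile 22.3, and complement genes in FAP-like cells 0.19 (-0.02 to 0.28) over 8. The 4 classes in which Adamts4 had a log2 ratio of at least 1 in size were endothelial-like, muscle stem cell-like, pericyte-like and smooth muscle-like, with ratios from -1.77 to -1.04.

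Saa3, Cxcl5, Lcn2, Tnc and Hp, several of them acute-phase genes, were nearly confined to the labelled-mobile library among FAP-like cells. The UMIs of Saa3, Cxcl5, Tnc and Hp came from 3, 3, 4 and 3 labelled-mobile cells, so these 4 describe a few cells. Tested first with the others and then alone, Lcn2 kept 106 UMIs in 13 cells against 0 without its 3 highest cells, a log2 ratio of -5.32 at the floor and at least 39.9-fold. RNA of neutrophils, which carry Lcn2, would bring S100a8 and S100a9 too, but 2 UMIs of these were seen against 25338 expected, or 0.00789%. A hypothesis is that some FAP-like cells of that pool may have been in an acute-phase state, and 1 muscle of the 6 in the pool could have supplied them, which was not tested.

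Has1, Ptgs2, Sfrp4, Myoc and Ugdh were higher in the labelled-immobile FAP-like cells, by sample labels that the file names contradict. The 5 highest cells of each gene in each library do not account for this. Without them the median log2 ratio of the 5 genes was 2.06, with single genes from 1.57 to 3.37. Leaving them out takes a larger part of the labelled-mobile cells that carried Has1, 26 against 50, so the size of this median is uncertain. A stronger dissociation response in the labelled-immobile library stays open. The immediate early median was 0.16 (0.04 to 0.23) with 7 of 14 members on each side. It was 0.29 (0.21 to 0.36) under the wider filter, outside the random lists. A larger share of Pi16-type cells stays open, as part or as the whole of the difference. The median within the Pi16-led cluster was 1.60, with single genes from 1.24 to 2.02, over 45 and 74 cells. Has1 and Ptgs2 are themselves among the genes that lead this cluster, and levels of Pi16-type markers were not compared within it. The value therefore cannot tell such a share apart from a difference in level. Pi16, Cd248, Mfap5, Pcolce2, Efemp1 and Fbn1 had a median of 0.75, with single genes from 0.40 to 0.87.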
